A study of Mus musculus with 20 samples.

How the data were processed

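CD8 T cells with the OT-I receptor, wild-type or Tet2 knockout, were profiled by droplet-based single-cell RNA sequencing (10x Chromium 3′ chemistry, version 2, per the labels' protocols) 8 days after transfer into mice with B16-OVA melanoma, with or without anti-PD-L1. There were 4 groups of 1 library. The series holds 20 samples, and the 8 RNA and 8 ATAC sequencing samples from earlier days were not analysed here.

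Each library came as a table of raw UMI counts deposited by the authors, with 1 row per barcode and 1 column per gene. A UMI, or unique molecular identifier, marks reads copied from the same captured molecule. The submitters' processing notes name the genome build mm10 and the tools Trim Galore 0.5.0, HISAT2, Bowtie2, Genrich 0.5, HTSeq, bedtools and DESeq2, without saying which were used for these tables. The counter, the annotation and the cell calling are not given in the sources used here. Every table listed most barcodes a second time, further down and with other counts. The second listing held 2384 barcodes in wild-type untreated, 1680 in wild-type with anti-PD-L1, 2312 in knockout untreated and 1346 in knockout with anti-PD-L1, and it contained 99.7%, 100%, 100% and 100% of the barcodes of the first. Log UMI totals of the same barcode correlated at 0.996 to 0.999 across barcodes, and the median over barcodes of the second total over the first was 1.03 to 1.05. The entries agreed less. Of the nonzero ones 50.6% to 80.6% differed, and profiles of the same barcode correlated at 0.798 to 0.940, least closely in wild-type untreated. Which listing the authors used is not stated. The second listing, which holds more barcodes, was used, and the first was tried as an alternative. Columns not shared by all 4 tables, and names with a hyphen followed by a digit from 1 to 4, were left out. That rule also drops real gene symbols of this form, among them the OT-I receptor segments planned as markers. At most 0.00289% of UMIs were left out in a library. In all, 27916 genes were used, of which 26935 matched an Ensembl symbol. Between 1 and 10 barcodes were shared by any pair of libraries. Coordinates come from RefSeq on GRCm38.p6, the assembly of mm10.

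Barcodes with at least 500 genes and at most 10% of UMIs on mitochondrial genes were kept. Under 500 genes were 26, 49, 49 and 57 barcodes and over 10% mitochondrial 70, 41, 71 and 36. Scrublet, run per library, called 14 doublets among 7722 barcodes, which is too few for the caller to have worked, so doublets remain in the data. The 7385 kept cells of the 4 libraries were scaled to 10000 UMIs, log-transformed, reduced to 2000 variable genes without T cell receptor and immunoglobulin segments and to 30 components, and clustered with 15 neighbours by the Leiden method at resolution 1.0, with no batch integration (scanpy 1.11.5, igraph 0.11.9). Of 13 clusters, 8 were taken as CD8 T cells, since their mean levels of CD8 and of CD3 genes were each at least 0.5 times that of the highest cluster. The rule also asked that no other lineage lead. This was checked only after the results were seen and only in the main setting, as mean marker folds over the other clusters, and no list that the rule names led in any of the 8. Globin genes, which it does not name, led in clusters 3 and 6 (1.19 and 2.44). Other cell types and CD8 states were named from marker lists fixed before the data were examined. Cluster 7, named progenitor-like from Tcf7, Klf2 and Slamf6, also holds a few cells led by Gzmg, Gzmd and the mast cell gene Cma1, which other settings put in a cluster of their own outside the CD8 T cells.

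UMIs of each library's CD8 T cells were summed and divided by their total to give CPM, the gene's share of UMIs on the usual scale. Folds are ratios of these, with exact conditional binomial 95% intervals (scipy 1.17.1), which cover counting error only. UMIs in a single cell are not independent, so intervals of genes held by few cells are too narrow. A count of 0 was set to 3 for a fold. With 1 library per group no comparison of groups was tested, and the results give no p-value. An additive fit over the 4 libraries was run only as an alternative count of genes. Genes were counted by a rule of size, a mean of at least 20 CPM over the 4 libraries and a 1.5-fold difference. The genotype comparisons with and without treatment share no library, nor do the treatment comparisons by genotype, so agreement within each pair was set beside the number expected for independent lists. Median folds of 16 gene lists were placed among 10000 random lists of the same size matched on level. Random lists draw each gene independently, whereas members of a list may move together. Percentiles therefore describe these libraries and are no test. Shares of cells have exact (Clopper-Pearson) binomial intervals. For shares of cells with a UMI, every cell was thinned to 2600 UMIs, close to the depth of the shallowest CD8 T cells, which left out 477 of 5063 CD8 T cells.

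Named genes were chosen by a rule fixed before the data were examined. It took up to 12 genes higher and 12 lower with the largest smaller fold across both genotype comparisons, 8 and 8 across both treatment comparisons, 5 and 5 with the widest gaps between the genotype folds, a fixed set of T cell genes, and up to 4 members of each list. One gene of the fixed set is not reported here. Receptor segments, sex-linked, haemoglobin, mitochondrial and ribosomal protein genes and markers of other cell types were left out of the ranked picks. Some of them are given apart, but no receptor segment or mitochondrial gene is. Named after their values were seen, as members of lists or counts, were Anxa1, Bach2, Bcl2l11, Ccdc28b, Ccl1, Ccl3, Ccnb1, Cd200, Cdc20, Cdc45, Fasl, Irf1, Klf2, Lgals3, Plk1, Rrm1, Satb1, Tsc22d3, Txk and Vamp5.

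Folds and counts were tested on simulated data, drawn for 5160 genes with 200 changed. The intervals, less the median shift, held the true fold for 94.8% of genes, all genes changed 2-fold or 4-fold were recovered and 1 unchanged gene passed the rule in a comparison. The draws were Poisson counts around a shared profile, with no spread between cells or libraries. They check the arithmetic and give no rate of false calls for the real libraries. Alternatives changed one choice at a time, except the stricter filter and equal depth and number of cells, which changed 2 together. They were TMM factors (edgeR 4.0.16 in R 4.3.3), equal weight for each cell, a floor of 50 CPM or of 30 UMIs, a 2-fold threshold, a stricter filter of 1000 genes and 5% mitochondrial UMIs, no doublet removal, all kept cells, a gate on each cell's own markers, no cycling-like clusters, Leiden resolutions of 0.5 and 1.5, clustering without cell cycle genes or on thinned cells, and an additive edgeR quasi-likelihood fit of genotype and treatment with 1 residual degree of freedom, which takes any interaction as error. The gate took cells with a UMI of CD8 and CD3 genes and none of the macrophage, B cell or melanoma lists. Those lists include Ly6c2, Ccr2 and Ighm. CD8 T cell clusters themselves held Ly6c2 at 534 to 2165 CPM and Ighm at 82.9 to 383. The gate therefore leaves out most CD8 T cells and selects among them. Added after the data were seen were the first listing, the gate without Ly6c2 and Ccr2, equal depth and number of cells, another linear algebra kernel, and each gene without its highest cell. Clustering depends on that kernel in its last digits, and another kernel gave 15 clusters. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0 was used, and matplotlib 3.10.9 drew the plots.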

Results

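The series asks how loss of Tet2, an enzyme that oxidises 5-methylcytosine in DNA, acts on T cells that have entered a tumour. CD8 T cells carrying OT-I, a transgenic receptor for a peptide of ovalbumin, came from wild-type or Tet2 knockout mice and were transferred into mice bearing B16-OVA, a melanoma line that makes ovalbumin. Cells were collected 8 days after transfer, with or without an antibody that blocks PD-L1, the ligand of the inhibitory receptor PD-1. The 4 groups analysed here were wild-type untreated, wild-type with anti-PD-L1, knockout untreated and knockout with anti-PD-L1. Each group was 1 library of droplet-based single-cell RNA sequencing, so nothing below has replicates. Intervals cover counting error only, and every difference is between libraries, not between tested conditions. The other 16 samples of the series, 8 of RNA sequencing and 8 of ATAC sequencing, were not analysed here.

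The listing of barcodes used here held 16209103 UMIs in wild-type untreated, 11986451 in wild-type with anti-PD-L1, 13826239 in knockout untreated and 11835704 in knockout with anti-PD-L1. After filtering there were 2289, 1602, 2219 and 1275 cells in that order, with median depths of 5154, 5536, 4712 and 7473 UMIs. CD8 T cells made up 49.3%, 83.5%, 70.6% and 80.9% of them, which gave 1128, 1337, 1567 and 1031 CD8 T cells. They were chosen by CD8 and CD3 levels, so CD8 T cells of the host may be among them. OT-I receptor segments, planned as markers, were left out by the rule on column names and not examined. Cells resembling melanoma, with pigment cell genes such as Mlana among the leading ones, were 40.2%, 4.31%, 8.56% and 3.92% of kept cells. Macrophage-like cells, led by the complement genes C1qa and C1qb, were 8.91%, 10.8%, 18.2% and 14.2%. How the tumours were dissociated and enriched can set these shares. The CD8 T cells held 4869765, 8280428, 8032296 and 8068839 UMIs, and all gene values below are sums over them, in CPM, UMIs of a gene scaled to the library's total. A gene was counted as higher or lower when its mean level over the 4 libraries was at least 20 CPM and the libraries differed at least 1.5-fold. The floor left 4628 genes.

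Tet2 transcripts stood at 13.6 CPM in wild-type untreated, 15.7 in wild-type with anti-PD-L1, 23 in knockout untreated and 18 in knockout with anti-PD-L1. The log2 fold of knockout over wild-type was 0.77 (95% interval 0.35 to 1.19) untreated and 0.19 (−0.16 to 0.55) with anti-PD-L1. These counts come from the 3′ end of the transcript, and the labels do not say which part of the gene was deleted. The level therefore checks nothing about the knockout. Tet3, a related enzyme, was at 14.4, 20.3, 21.8 and 20.2 CPM, with log2 folds of knockout over wild-type of 0.60 and −0.01, and Tet1 was below 1 CPM in each library. The list of TET and DNA methylation genes had 4 members past the floor and median log2 folds of −0.20 untreated and 0.16 with anti-PD-L1, within the range of random lists (percentiles 30.3 and 70.5).

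The wild-type untreated CD8 T cells stood apart from the other 3 libraries. Between them and wild-type cells with anti-PD-L1, 1471 of the 4628 genes differed 1.5-fold, against 683 for knockout untreated and 1025 for knockout with anti-PD-L1. The pairs without that library differed at 363, 186 and 124 genes. Both comparisons that use it, the untreated genotype comparison and the wild-type treatment comparison, therefore share whatever sets it apart.

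**Figure D1:**
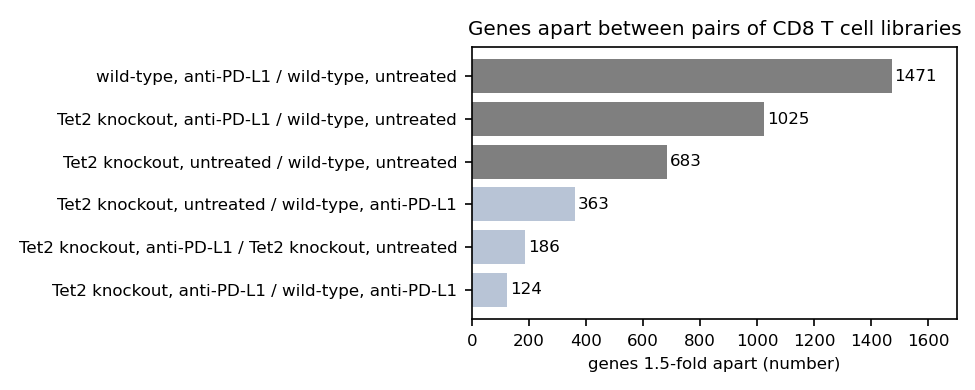
Each bar gives the number of genes, of 4628 compared, that differed at least 1.5-fold between a pair of CD8 T cell libraries, with pairs that hold the wild-type untreated library in grey. Those pairs reach 683 to 1471 genes, and the others 124 to 363.

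Untreated knockout cells held more transcripts of the T cell receptor signalling list than untreated wild-type cells. Effector genes split, and the medians of cell cycle lists were lower, with most of their members less than 1.5-fold apart. Dusp5, a phosphatase induced by receptor signalling, was at 24.4 CPM in wild-type and 130 in knockout, a log2 fold of 2.41 (2.13 to 2.69). The chemokine Ccl5 was at 476 and 2133 (2.16, interval 2.10 to 2.23), and granzyme A, a cytotoxic protease encoded by Gzma, at 59.8 and 384 (2.68, 2.51 to 2.86). Mitotic kinase Plk1 had a log2 fold of −1.34, cyclin Ccnb1 of −1.07 and Cdc45, a replication factor, of −0.91. In all, 369 genes were higher and 314 lower in knockout. Scaling by TMM factors in place of library totals gave 441 higher and 219 lower, and moved the median of all genes from −0.10 to −0.02 on the log2 scale. Lower genes outnumbered higher ones without cycling-like clusters (525 higher and 693 lower) and with a stricter cell filter (487 and 573). With all kept cells in place of CD8 T cells the counts were 776 and 949, and the directions of Cd83, Capg, Id3, Slamf6, Hspa1a and AA467197 turned.

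Among the lists fixed before the data were examined, T cell receptor signalling and early activation stood highest in untreated knockout cells, with a median log2 fold of 0.87 and 13 of 19 measured members higher against 1 lower. Its members included Nfkbia, an inhibitor of NF-κB that NF-κB itself induces (1.71), the co-stimulatory receptor gene Tnfrsf9 (0.60) and the interleukin-2 receptor chain Il2ra (1.12). The median lay above all 10000 random lists matched on level. Genes of such lists are drawn independently, while list members may move together, so the percentile is a description only. In macrophage-like cells of the same libraries, the immediate early and heat shock list had a median of 0.62, and in melanoma-like cells 0.02. Receptor signalling was therefore not told apart from a response, such as to handling, shared with other cells. Interferon response genes had a median of 0.54 with 8 of 19 higher and none lower, including Isg15 (1.08, 0.68 to 1.49), Irf1 (1.23) and Socs1 (0.99). Cytotoxic effector genes had a median of 0.36 and split, with 8 of 17 higher and 3 lower. Gzma, the inhibitory NK receptor gene Klrc1 (0.85) and the death ligand Fasl (1.83) were among the higher members, whereas Gzmc (−3.99), Gzmf (−4.46) and Gzmd (−4.46) were lower. The Gzmd fold compares 19 wild-type cells with 1 knockout cell that held all 23 UMIs. Gzmd was also among the leading genes of a few cells that other settings put outside the CD8 T cells. Perforin, encoded by Prf1 and below the floor with a mean of 18.5 CPM, had a log2 fold of −1.02 (−1.45 to −0.60) and Gzmb of 0.08 (0.04 to 0.13). Of 9 cytokine and chemokine genes, 2 were higher and 1 lower, with a median of 0.42, and Ifng had a log2 fold of 0.12 (0.01 to 0.24). Without its highest cell per library that fold of Ifng was 0.44, as in wild-type untreated this cell held 232 of 923 UMIs. Homing and adhesion genes had a median of 0.37 with 5 of 17 higher, such as the chemokine receptors Cxcr6 (1.04) and Ccr2 (1.66). With a gate on each cell's own markers, which kept 49 and 67 cells, the homing median was −0.13. That gate leaves out cells with a UMI of Ly6c2, Ccr2 or Ighm, which CD8 T cells also hold, so its cells are a selected part. Apoptosis and survival genes had a median of 0.49 with 5 of 13 higher, among them the kinase gene Pim1 (1.94) and the pro-apoptotic Bcl2l11 (1.24).

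Inhibitory receptors did not move as a block in the untreated genotype comparison. The list of exhaustion genes had a median log2 fold of 0.48, above nearly all matched random lists, but its members went both ways. Ctla4 was at 119 CPM in wild-type and 242 in knockout (1.02, 0.89 to 1.16) and Lag3 at 252 and 356 (0.50). Pdcd1, which encodes PD-1, was at 313 and 241 (−0.38, −0.48 to −0.28), Havcr2, which encodes TIM-3, was at 25.1 in each, and Tox, a transcription factor of the exhausted state, was at 112 and 49.1 (−1.19, −1.38 to −1.0). Memory genes also split, with 6 of 14 higher and 2 lower and a median of 0.35, again above nearly all random lists. With the gate that kept 49 and 67 cells that median was −0.03. Ccr7, a receptor for homing to lymph nodes, stood at 227 and 456, and Satb1 (1.76), Bach2 (1.44), Klf2 (0.72) and Il7r (0.91) were also higher. Tcf7, the transcription factor of progenitor-like T cells, was at 98.8 and 89.5 (−0.14, −0.31 to 0.03), and Slamf6 had a log2 fold of −0.67.

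Cell cycle lists lay below all matched random lists in untreated knockout cells. S phase genes had a median of −0.43 with 5 of 23 lower, including Rrm1 (−0.73), and G2/M genes had −0.45 with 9 of 25 lower, including Cdc20 (−1.15). Mki67, a marker of dividing cells, differed little, with a log2 fold of 0.06 that became −0.11 with each cell weighted equally. Glycolysis genes had a median of −0.20 (percentile 10.3), with Ldha, which makes lactate, at 3141 and 2079 CPM. Oxidative phosphorylation genes had −0.22 (percentile 0.73), MHC class I genes 0.00 and ribosomal protein genes 0.09. Transcripts that respond to tissue handling moved in this comparison too, with a median of 0.47 over the immediate early and heat shock list, 9 of 20 members higher and 2 lower. Fos and Zfp36 had log2 folds of 1.03 and 1.64, and Hspa1a, a heat shock chaperone, of −0.92, which turned to 0.92 with a gate that kept 49 and 67 cells.

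With anti-PD-L1, knockout and wild-type CD8 T cells were far closer. There, 53 genes were higher and 71 lower in knockout, or 27 and 85 with TMM factors. Cell cycle lists now lay on the other side, with a median log2 fold of 0.38 over S phase genes and 0.28 over G2/M genes, each above all matched random lists, though only 1 of 23 and 4 of 25 members were higher. Plk1 (0.75), Ccnb1 (0.73) and Cdc45 (0.71) were among these, while Pcna (0.51) and Mki67 (0.34, 0.17 to 0.50) stayed under 1.5-fold. The sign of the G2/M median turned to −0.28 when cycling-like clusters were left out. Memory genes had a median of −0.29, below all matched random lists, with 3 of 14 lower and none higher, among them Klf2 (−1.36), Ccr7 (541 and 350 CPM, −0.63) and Slamf6 (−0.96). Tcf7 was at 56.9 and 37.9 (−0.58, −0.80 to −0.37).

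Effector genes did not move together with anti-PD-L1. The cytotoxic list had a median of −0.11 (percentile 0.07) with 2 of 17 lower, Gzmf and Gzmc, and none higher, and cytokines had 0.13 (percentile 86) with Ccl1 lower (−1.14). Gzmb was at 2059 and 2718 CPM (0.40, 0.37 to 0.43), Prf1 at 16.4 and 24.7 (0.59, 0.26 to 0.91) and Ifng at 295 and 423 (0.52, 0.45 to 0.60). A gate on each cell's own markers, which kept 28 to 67 cells per library, turned Gzmb (−0.46) and Ifng (−1.90), and Ifng turned also (−0.27) with a gate without Ly6c2 and Ccr2 that kept 545 and 321 cells. Both gates leave out CD8 T cells that hold Ighm, and the first also those with Ly6c2 or Ccr2. Their folds are of selected cells. Exhaustion genes had a median of −0.05 with none of 8 apart. Pdcd1 had a log2 fold of −0.12 (−0.20 to −0.05), Ctla4 of 0.15 (0.08 to 0.23), Havcr2 of 0.14 (−0.04 to 0.32) and Tox of −0.37 (−0.59 to −0.15). Lag3 was close to 0 at 0.06 and its sign turned with TMM factors. T cell receptor signalling (−0.04), interferon response (−0.01), MHC class I (−0.07), homing (−0.07, with Lgals3 at −0.83), apoptosis (0.09), oxidative phosphorylation (0.07) and ribosomal protein genes (−0.03) had medians near 0. As most genes lay slightly above 0 here (median 0.09), receptor signalling, homing, MHC class I and ribosomal genes were below nearly all matched random lists (percentiles 0.21 to 0.72). Glycolysis genes had 0.21 (percentile 99.55), with Ldha at 0.36. Immediate early and heat shock genes had 0.03, which became −0.03 with TMM factors, although Hspa1a was higher (1.70).

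Across both genotype comparisons, which share no library, 10 genes were higher and 23 lower in knockout each time, where independent lists would share 4.23 and 4.82. Opposite directions exceeded independence as well, with 21 and 14 genes against 5.66 and 3.60, so the excess alone is no sign of agreement. A floor of 50 CPM left 2 higher and 11 lower, and all kept cells gave 74 higher. Across all 4628 genes the folds of these comparisons ran weakly opposite (Pearson r −0.134, Spearman rho −0.260, across genes, which are not independent replicates). Transcripts of Y-linked genes were found in 10.8% (9.06% to 12.8%) of wild-type untreated and 14.1% (12.2% to 16.0%) of wild-type CD8 T cells with anti-PD-L1, but in 0.128% of knockout untreated cells and 0 of 1031 with anti-PD-L1, which by the rule of 3 counts allows up to 0.291% of cells with such a UMI. Among cells with Xist, the RNA of the inactive X, and no Y-linked UMI, 30 of the 33 genes were still 1.5-fold apart in both comparisons. The others were Cd7, BC035044 and Erdr1, and all 33 kept their direction.

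Higher in knockout in both comparisons was Gm156, now named Klrh1, of the killer cell lectin-like receptor family. It lies on chromosome 6 at 129766568 to 129784270 (GRCm38, the same build as mm10), and was at 64.1 and 191 CPM untreated (1.58, 1.40 to 1.76) and 91.1 and 276 with anti-PD-L1 (1.60, 1.48 to 1.72). The gate on each cell's own markers turned its untreated fold to −1.22. Klri2 on chromosome 6 at 129729041 to 129740484, another receptor of that family, had log2 folds of 1.85 (1.36 to 2.37) and 1.13 (0.84 to 1.43). BC035044 lies nearby at 128848044 to 128891124 and had 0.62 and 1.39, but its untreated fold turned to −0.14 with the gate without Ly6c2 and Ccr2. Cd7, a T cell surface protein, was at 4.52 and 22.9 untreated (2.34, 1.70 to 3.05) and 27.1 and 41 with anti-PD-L1 (0.60). Without its highest cell per library, the Cd7 fold with anti-PD-L1 was 0.577, just under 1.5-fold. Cables1 had 1.81 and 0.60, Tnip3, an inhibitor of NF-κB signalling, 0.64 and 0.68, and Atp10a 0.59 and 0.71. Tpm3-rs7 (3.01 and 2.90) and Gm10036 (2.07 and 2.08) had the largest folds held in both comparisons but resemble copies of other genes, so reads shared with those copies leave them uncertain. Erdr1 (0.67 and 1.27) lies in the region shared by the X and Y chromosomes.

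Among the 23 genes lower in knockout were a granzyme, a tetraspanin and metallothioneins. Gzmf, on chromosome 14 at 56205263 to 56211407, was at 84.8 and 3.86 CPM untreated (−4.46, −5.03 to −3.93) and 45.5 and 6.82 with anti-PD-L1 (−2.74, −3.18 to −2.33). Its UMIs came from few cells, 37 and 52 in the wild-type libraries and 5 and 20 in the knockout ones, in the order untreated and anti-PD-L1. Gzmc, its neighbour at 56231397 to 56241647, had −3.99 and −0.60. Gzmg met the same rule (−4.44 and −1.06), but 394 of its 395 UMIs in wild-type untreated came from a single cell, as did all 30 in knockout untreated and all 35 in knockout with anti-PD-L1, so its folds compare single cells. Gzmg also led, with Gzmd, the few cells that other settings put outside the CD8 T cells. The granzymes of this cluster are near-identical, so reads may be split between them. Cd81, a tetraspanin of the cell surface, on chromosome 7 at 143052750 to 143067930, was at 66.3 and 9.71 untreated (−2.77, −3.15 to −2.41) and 20.4 and 4.46 with anti-PD-L1 (−2.19, −2.76 to −1.67). Its fold with anti-PD-L1 turned to 0.10 over all kept cells. Dapl1, on chromosome 2 at 59484653 to 59505020, a gene of naive and memory-like T cells, had −2.02 (−2.16 to −1.88) and −1.87 (−2.11 to −1.62).

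The metal-binding proteins Mt1 (500 and 290 CPM untreated, −0.79; 739 and 442 with anti-PD-L1, −0.74) and Mt2 (−1.06 and −0.86) lie together on chromosome 8. The actin-capping protein gene Capg had −0.82 (−0.93 to −0.71) and −0.95 (−1.04 to −0.86), Cd83 −0.86 and −1.33, and Decr1, an enzyme of fatty acid oxidation, −0.96 and −0.81. Less was also found in knockout of Cd200, Slamf6, Txk, Vamp5, Ccdc28b, AA467197, Toporsos and Gm10263. Transcripts given apart also moved with genotype. Of 82 ribosomal protein genes 4 were lower untreated and 3 with anti-PD-L1, and 1 higher each time. Lower in both were Rps29, at 3692 and 1889 CPM untreated (−0.97) and 6483 and 3655 with anti-PD-L1 (−0.83), Rpl38 (−0.94 and −0.61) and Rps28 (−0.86 and −0.60). Lower too were genes that also mark other cells, Cd74 of antigen-presenting cells (−1.59 and −0.82) and Fcer1g of macrophages and NK cells (−0.65 and −1.41). Melanoma markers in CD8 T cells, a measure of free RNA, stood at 0.579%, 0.111%, 0.157% and 0.0777% of their level in melanoma-like cells, highest in wild-type untreated. Macrophage markers stood at 0.120%, 0.102%, 0.148% and 0.104% of their level in macrophage-like cells, highest in knockout untreated.

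**Figure D2:**
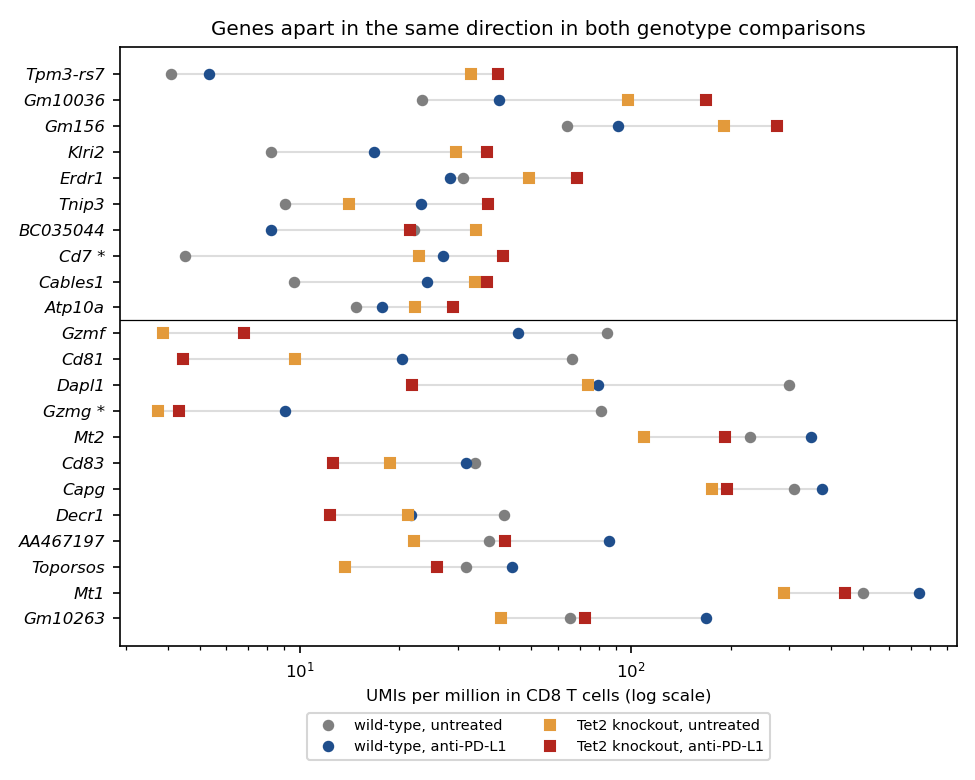
Points give CPM in CD8 T cells, on a log axis, of the named genes apart in the same direction in both genotype comparisons, with circles for wild-type and squares for knockout and genes higher in knockout above the line. Gm156 stands at 64.1 and 91.1 in wild-type against 191 and 276 in knockout, and Cd81 at 66.3 and 20.4 against 9.71 and 4.46. Asterisks mark Gzmg and Cd7, which without the highest cell of each library were not 1.5-fold apart in the same direction in both comparisons. Gzmg rests on single cells, whereas Cd7 fell just short with anti-PD-L1.

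In wild-type cells, the library with anti-PD-L1 held more transcripts of chemokines, receptor signalling and interferon response, and fewer of cell division. Ccl5 was at 476 CPM untreated and 5039 with anti-PD-L1 (3.40, 3.34 to 3.47), Gzma at 59.8 and 838 (3.81, 3.64 to 3.98), and Ifitm1, an interferon-induced membrane protein, at 10.1 and 279 (4.79, 4.38 to 5.23). There were 530 genes higher and 941 lower, or 699 and 631 with TMM factors, which moved the median of all genes from −0.18 to −0.05. Percentiles among matched random lists place each list relative to that shift. Over all kept cells, where melanoma-like cells were 40.2% of the untreated library, the folds of Id3, Slamf6, Tcf7, Lef1, Isg15 and other named genes turned.

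Exhaustion genes had a median log2 fold of 1.03 in this comparison, with 6 of 8 higher and 1 lower. Havcr2 was at 25.1 and 58.1 (1.21, 0.92 to 1.51), Lag3 at 252 and 453 (0.85), Ctla4 at 119 and 303 (1.34), Rgs16 at 79.9 and 282 (1.82) and Pdcd1 at 313 and 393 (0.33, 0.24 to 0.41), whereas Tox was at 112 and 47.5 (−1.23, −1.43 to −1.05). Receptor signalling genes had 1.08 with 14 of 19 higher and 1 lower, including Dusp5 (3.31, 3.04 to 3.59), Nfkbia (1.74) and Tnfrsf9 (1.08). Cytotoxic genes had 0.72 with 12 of 17 higher, including Gzmb (0.62), Nkg7 (0.72) and Klrc1 (1.48), and 3 lower, and Prf1, below the floor, had −0.42. Cytokines had 0.92 with 6 of 9 higher and 1 lower, the higher including Xcl1 (0.97) and Ifng (0.64, or 0.91 without its highest cell per library). Interferon genes had 0.94 with 14 of 19 higher and none lower, including Isg15 (2.17) and Ly6c2 (1.57). Homing genes had 0.67 with 9 of 17 higher and 1 lower, the higher including Cxcr6 (2.22) and S100a4 (1.96), and apoptosis genes 0.61 with 7 of 13 higher. MHC class I genes had 0.23 (percentile 99.3) with 3 of 19 higher and 1 lower, and B2m was at 3403 and 4933. Immediate early and heat shock genes had 0.70 with 10 of 20 higher and 4 lower. In macrophage-like cells that list had 1.15 and in melanoma-like cells 0.04. A response shared with other cells was therefore not told apart from receptor signalling.

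S phase genes were lower with anti-PD-L1 in wild-type cells, with a median of −0.97 and 21 of 23 lower (below all matched random lists), and so were G2/M genes, with −1.01 and 23 of 25 lower. Examples are Cdc45 (−1.41), Ccnb1 (−1.83) and Dut, which keeps uracil out of DNA (676 and 319 CPM, −1.08). Memory genes split with 6 of 14 higher and 5 lower and a median of 0.28. Ccr7 (1.25), Satb1 (2.04) and Il7r (1.09) were higher and Id3 (−2.05), Tcf7 (−0.80) and Slamf6 (−1.03) lower. Glycolysis genes had −0.31 (percentile 8.52) with 4 of 14 lower, among them Ldha (−0.94), oxidative phosphorylation genes −0.28 with 3 of 39 lower, and DNA methylation genes −0.49 with the maintenance methyltransferase Dnmt1 lower (−0.77). Ribosomal protein genes had 0.08 with 10 of 82 higher and 1 lower, Rps29 among the higher (0.81).

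Knockout cells with and without anti-PD-L1 differed at fewer genes, 135 higher and 51 lower. The lower count rose to 112 without cycling-like clusters and to 137 over all kept cells, while the higher count stayed within 1.5 times. Some chemokine and effector genes again stood higher with anti-PD-L1. Ccl4 was at 557 and 1686 CPM (1.60, 1.55 to 1.65), Ccl5 at 2133 and 4338 (1.02), Gzmb at 1419 and 2718 (0.94, 0.90 to 0.97), Prf1 at 10.8 and 24.7 (1.19, 0.82 to 1.57) and Ifng at 207 and 423 (1.03, 0.95 to 1.12). The same small gate, with 67 and 28 knockout cells, turned Gzmb (−0.53), Ifitm1 (−1.24), Gzma (−2.49), Ccl5 (−0.08) and Pdcd1 (−0.09) and the cytokine list. Cytokines had a median of 0.73 with 5 of 9 higher and cytotoxic genes 0.51 with 7 of 17 higher, with none lower in either list. Havcr2 was at 25.1 and 63.9 (1.35, 1.11 to 1.59), Pdcd1 at 241 and 361 (0.58, 0.50 to 0.67), and the exhaustion list had 0.44 with 2 of 8 higher. Receptor signalling (0.22), interferon response (0.32), homing (0.29, 6 of 17 higher) and apoptosis genes (0.39) also lay above nearly all matched random lists. Memory genes had −0.29 with 5 of 14 lower and none higher, including Slamf6 (−1.33), Tcf7 (89.5 and 37.9, −1.24), Id3 (−1.37) and Klf2 (−0.75). S phase (−0.17) and G2/M genes (−0.19) lay below nearly all matched random lists but had no member 1.5-fold apart. Glycolysis (0.11, percentile 96.5), MHC class I (0.13, percentile 98.8), immediate early and heat shock (0.12, percentile 98.7), DNA methylation (−0.07), oxidative phosphorylation (−0.00) and ribosomal protein genes (−0.08, with 11 of 82 higher, Rps29 at 0.95) lay close to 0.

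Across both treatment comparisons, 94 genes were higher and 25 lower with anti-PD-L1 each time, where independent lists would share 15.5 and 10.4, and the folds ran together across genes (Pearson r 0.469, Spearman rho 0.457). Genes higher in both included Ccl4 (2.30 in wild-type), Fosb, part of the AP-1 transcription factor (3.98 and 1.44), Lfng, a modifier of Notch receptors (2.96 and 1.34), Ifitm1 (4.79 and 1.23), Lilrb4a, an inhibitory receptor (9.45 and 26.8 in wild-type, 15.1 and 39.4 in knockout), Tnip3 (1.36 and 1.40), Gm12840 (2.25 and 1.31) and Havcr2. Lower in both, among others, were Dapl1 (−1.91 and −1.76), Id3, Cd81 (−1.70 and −1.12), Slamf6, Tcf7, Slc36a3os (−0.80 and −0.99) and Ubac2 (−0.86 and −0.80). Cd8a was at 568, 807, 778 and 819 CPM in the 4 libraries. Tigit (0.821, 1.45, 2.24 and 3.72), Tnf (2.87, 11.6, 8.59 and 11.5) and Cd274, which encodes PD-L1 (4.72, 12.8, 6.72 and 12.5), had few counts.

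**Figure D3:**
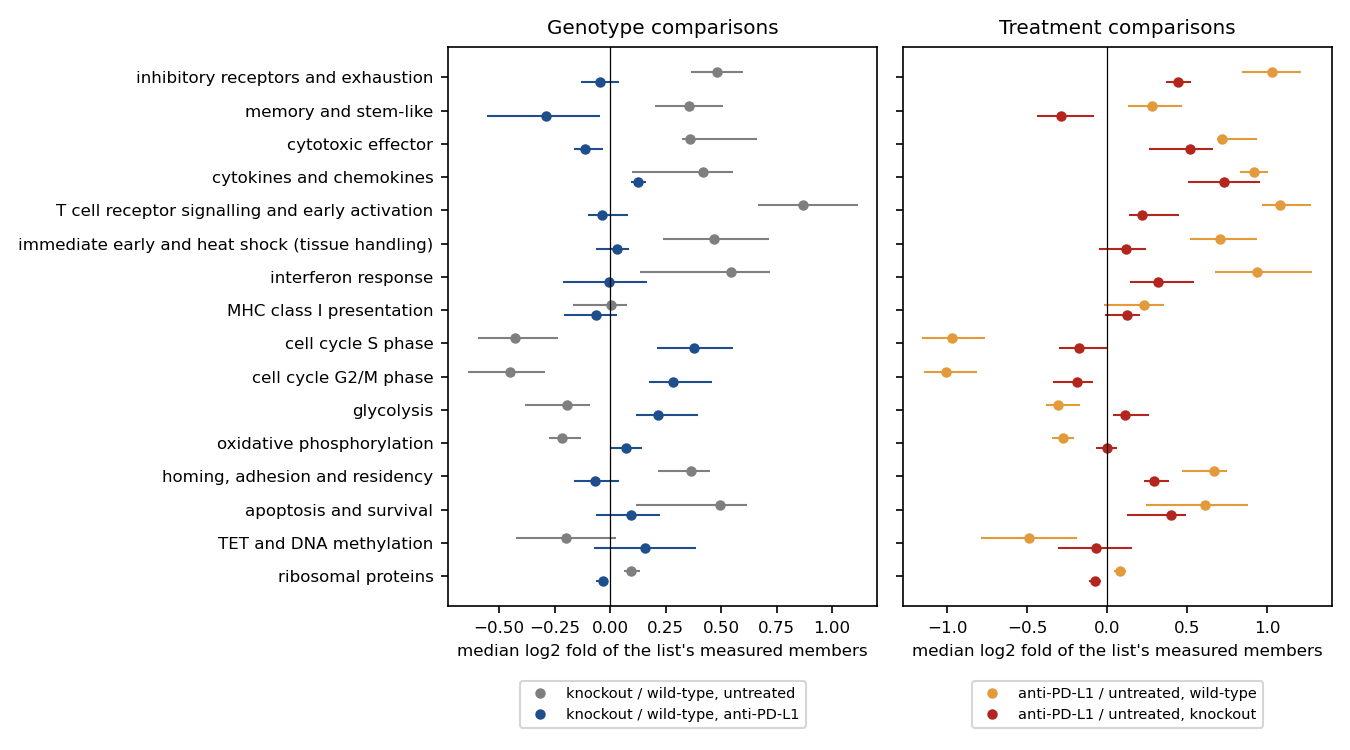
Points give the median log2 fold of each gene list's measured members in the genotype (left) and treatment (right) comparisons, and lines run between the medians of the members' 95% counting bounds. S phase genes stand at −0.43 and 0.38 in the genotype comparisons and at −0.97 and −0.17 in the treatment comparisons.

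The genotype comparisons went in opposite directions for some genes. Higher in untreated knockout and lower with anti-PD-L1 were 21 genes, where independent lists would share 5.66, among them Klf2, Ccr7, Ifitm1, Anxa1 (0.99 and −1.05), Tsc22d3, a glucocorticoid-induced gene, and the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, which come from red blood cells. The 14 genes with the opposite pattern, against 3.60, included Plk1, Ccnb1, Cdc45, Hspa1a and Serpinb9b (−1.72 and 0.70). Hbb-bt had folds of 2.11 and −3.49. With globin genes left out, the widest gaps between the untreated and anti-PD-L1 genotype folds were those of Ifitm1 (2.84 and −0.72), Gadd45b, a stress response gene (3.53 and 0.00), Fosl2 (3.21 and −0.26), Cnih2 (2.97 and −0.18) and Nfkbid (3.18 and 0.19) on the upper side. On the lower side were Gzmd (−4.46 and 0.43), Gzmc, Gzmg, Hspa1a (−0.92 and 1.70) and Serpinb9b. Gzmd rested on few cells. Its highest cell held 217 of 307 UMIs in wild-type untreated, all 23 in knockout untreated and 179 of 242 in knockout with anti-PD-L1. Its fold with anti-PD-L1 was −1.03 with each cell weighted equally. Treatment comparisons went opposite ways for 5 genes in each direction, against 5.84 and 27.4 for independent lists.

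Shares of CD8 T cells with a UMI were compared after each cell was thinned to 2600 UMIs, which left 910, 1255, 1412 and 1009 cells and dropped 218, 82, 155 and 22. Before thinning the median depths of CD8 T cells were 3748.5, 5368, 4396 and 6807 UMIs, those of macrophage-like cells 3003.5, 5914, 4806 and 9110, and those of melanoma-like cells 10222, 25574, 13918 and 31762.5. Pdcd1 was found in 51.1% (47.8% to 54.4%), 53.5% (50.7% to 56.3%), 40.4% (37.9% to 43.1%) and 51.8% (48.7% to 55.0%) of cells, in the order wild-type untreated, wild-type with anti-PD-L1, knockout untreated and knockout with anti-PD-L1, and in 3.41% to 7.53% of macrophage-like cells thinned alike. Without thinning the shares were 64.4%, 69.3%, 53.2% and 74.4%. Havcr2 was found in 5.38%, 14.0%, 6.87% and 16.7%, and in 8.95%, 23.6%, 10.5% and 31.0% without thinning. Macrophages express this gene too, and 3.42% to 12.8% of macrophage-like cells had it. Lag3 was in 43.3%, 63.1%, 59.2% and 67.1% (unthinned 59.5%, 80.7%, 75.4% and 88.8%) against at most 1.32% of melanoma-like and 8.90% of macrophage-like cells. Ctla4 was in 24.2%, 51.5%, 44.3% and 50.4% (unthinned 37.8%, 71.5%, 60.6% and 74.9%) against 2.74% to 4.94% of macrophage-like cells.

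Tcf7 was found in 20.8%, 11.1%, 17.0% and 8.23% of thinned cells (unthinned 29.0%, 19.3%, 25.9% and 15.6%), above the 0% to 1.6% of melanoma-like cells and the at most 4.79% of macrophage-like cells. Tox was in 23%, 10.7%, 12.2% and 8.72% (34.2%, 19%, 20% and 20.1%) against at most 3.42% of macrophage-like cells. Gzmb was in 46.3%, 65.7%, 54.6% and 75.8% (49.0%, 71.7%, 61.9% and 81.3%) against 6.16% to 12.3% of macrophage-like cells. Ifng was in 18.1%, 22.5%, 21.5% and 30.8% (23.4%, 33.5%, 29.0% and 46.5%) against 1.23% to 2.89%, Mki67 in 21.1%, 10.7%, 19% and 11.8% (30.2%, 21.0%, 30.8% and 30.0%) against at most 7.53%, and Prf1 in 5.27%, 4.3%, 2.62% and 5.25% (8.33%, 8.6%, 4.91% and 13.6%) against at most 0.617%, each in macrophage-like cells. Il7r was in 5.16%, 12.6%, 11.2% and 10.8%, against 2.05% to 11.1% of them. Tnf, at 0.44%, 2.87%, 1.7% and 2.68%, and Tet2, at 4.18%, 4.38%, 5.74% and 5.75%, were below the shares in macrophage-like cells of the same library. Tigit was in under 1% of thinned cells in each library.

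**Figure D4:**
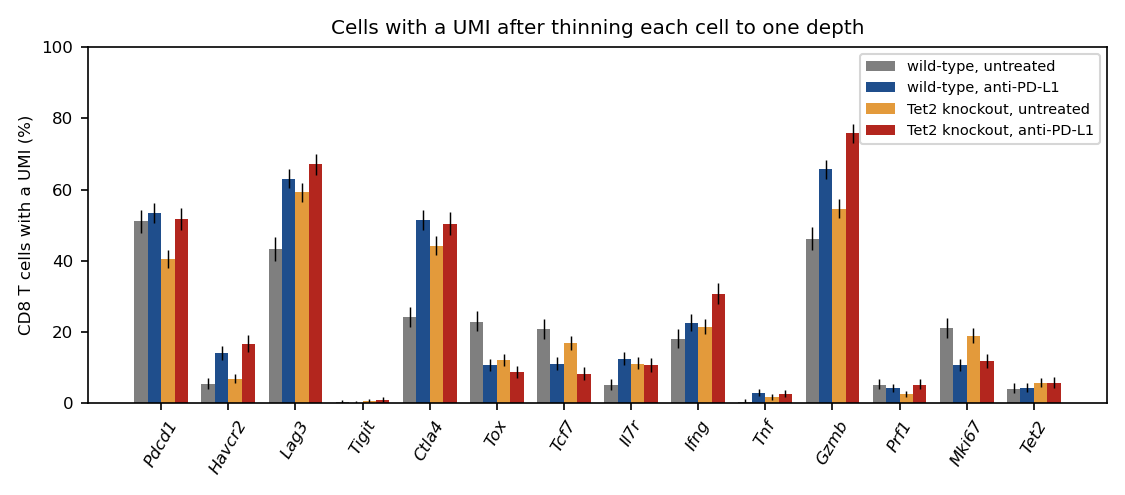
Bars give the percent of CD8 T cells with at least 1 UMI of each gene after thinning to 2600 UMIs per cell, by library, with exact 95% binomial intervals. Gzmb runs from 46.3% in wild-type untreated to 75.8% in knockout with anti-PD-L1, and Tcf7 from 20.8% to 8.23%.

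Clusters of CD8 T cells were named from markers fixed in advance. Progenitor-like clusters, numbered 6 and 7 and named for Tcf7 and Slamf6 among their leading genes, held 58.9%, 20.5%, 21.6% and 10.5% of CD8 T cells in the order above. Cluster 6 was led by Dapl1 and globin genes and cluster 7 by Gzmg and Cma1. Cluster 7 also held NK cell genes, such as Klra4 at 30.9 CPM. It held Tyrobp at 148 CPM too, a gene at 3221 CPM in the macrophage-like cluster. Cycling-like clusters, with Birc5 and Mki67 among their leading genes, held 4.08%, 19.8%, 42.2% and 31.4%. These shares do not count dividing cells, as Mki67 was at 124 CPM in cluster 6 and 86.7 in unnamed cluster 9, against 139 and 201 in the cycling-like clusters 5 and 8. A recently stimulated-like cluster with Ccl4, Ccl3 and Ifng among its leading genes held 0.177%, 29.4%, 13.7% and 27.4%, and unnamed clusters held 36.9%, 30.3%, 22.6% and 30.7%. Genes that define these clusters themselves differed between libraries, so the sizes are given as description and not compared. Cluster 6 drew 647 of its 766 cells from wild-type untreated, and cluster 9, led by Gzmc and Gzmf, 408 of its 514. Each may be that library and not a cell type. The progenitor-like share of wild-type untreated ranged from 6.07% to 62.2% over the alternative settings.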

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

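The test of the chromosome 6 region was chosen after its genes had been seen, and the depth test was changed from 1 draw to 20 after a first draw had been seen, and read against a ratio of 1 after all draws had been seen.

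Wild-type untreated CD8 T cells stood apart from the other 3 libraries, with 683 to 1471 genes 1.5-fold apart in its pairs against 124 to 363 in the others. Free RNA of melanoma cells is argued against as the whole cause, because without genes that melanoma-like cells hold at least 2-fold above CD8 T cells the lowest pair with that library still had 1.84 times the genes of the highest pair without it. Lower depth is argued against as the whole cause. With 910 cells per library and 2600 UMIs per cell the lowest such ratio of 20 draws was 1.38 and the highest 1.70, where depth alone would leave at most 1, and among genes at 100 CPM or more it was 1.65 without thinning. Some draws stayed under the 1.5 set beforehand as the bound against depth, so a part played by depth is open. A difference of that library or tumour as a whole remains open, since macrophage-like cells of the same libraries, which are host cells, showed a ratio of 2.75, though those of wild-type untreated held only 673464 UMIs and more melanoma RNA, such as Dct at 108 CPM against 8.07 to 13.7 in the others, and such a difference cannot be told apart from an effect on the tumour of the missing treatment and intact Tet2 with 1 library per group.

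The genotype comparisons with and without anti-PD-L1 pointed opposite ways for some genes, 21 higher in knockout untreated and lower with anti-PD-L1 and 14 the other way. The difference between the genotype folds was not tested, as there are no replicates. Both patterns involve the wild-type untreated library.

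Of the genes apart in the same direction in both genotype comparisons, Klri2, Gm156 and BC035044, 3 of 33, lie between 128848044 and 129784270 on chromosome 6, in the natural killer gene complex, where 0.100 would be placed by the density of compared genes. A donor haplotype of this complex, differing between the wild-type and knockout mice, is therefore a candidate explanation for those 3 genes, beside an effect of Tet2 itself, which was not tested apart from it. Untreated folds turned for Gm156 with the gate per cell (−1.22) and for BC035044 with the gate without Ly6c2 and Ccr2 (−0.14). Around Tet2 on chromosome 3, from 113463677 to 153545136, lay 0 of the 33 genes, against 0.330 by density. None of the 33 genes is therefore itself in a haplotype of that region. With so few placed there by density, the count cannot weigh such a haplotype further, nor effects it may have on genes elsewhere. Male cells in the wild-type libraries are argued against for most of the pattern, since 30 of the 33 genes stayed apart, and all 33 kept their direction, among cells with Xist and no Y-linked UMI. Those cells may include CD8 T cells of the host, which were not told apart from transferred ones.

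A signal outside the comparisons was Y-linked UMIs in 10.8% and 14.1% of wild-type CD8 T cells, untreated and with anti-PD-L1, against 2 of 1567 and 0 of 1031 knockout cells. Of 173 macrophage-like cells in wild-type with anti-PD-L1, 5 held such a UMI, 4 of them also with Xist. In wild-type untreated, knockout untreated and knockout with anti-PD-L1, 0 of 204, 0 of 404 and 0 of 181 macrophage-like cells did. The shares of CD8 T cells with Xist follow. Xist was found in 69.1% and 71.8% of the wild-type cells and 94% and 95.4% of the knockout cells. Wild-type cells with both numbered 5 and 17, where independence would give 84.3 and 135. The higher ratio, 0.126, is what a mix of male and female cells may give, as a hypothesis. Transferred CD8 T cells were not told apart from those of the host, so whether both sexes were among the donors is open. The sex of the donors is not in the labels, and beyond this mix no biological explanation was tested.

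The tables listed 2278, 1491, 2121 and 1270 barcodes a second time, in the order wild-type untreated, wild-type with anti-PD-L1, knockout untreated and knockout with anti-PD-L1. That second listing was used throughout.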

How the results depend on the processing

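Chosen after the data were seen were the first listing of barcodes, the gate without Ly6c2 and Ccr2, equal depth and number of cells, another linear algebra kernel, and each gene without its highest cell. A minimum of 30 UMIs for a gene fold under an alternative was also set after the alternatives had been seen. It left out 228 gene folds, 28 of them opposite in sign, of which 211 and 22 belonged to the gate per cell, and 21 list medians. No paired analysis was possible because each group has 1 library, so the groups share no more than 1 replicate number, and the main results come from no test.

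Counts of genes are given as pairs, higher then lower, for knockout over wild-type untreated and with anti-PD-L1, then anti-PD-L1 over untreated in wild-type and knockout, then both genotype and both treatment comparisons. Of 178 alternative counts, 108 stayed within 1.5 times. By construction fewer genes remained with a floor of 50 CPM (173 and 150, 10 and 31, 277 and 539, 73 and 22, 2 and 11, 55 and 12) and a 2-fold threshold (141 and 37, 7 and 17, 260 and 196, 34 and 10, 4 and 4, 21 and 5). More were compared with 30 UMIs in place of the floor (1136 and 918, 412 and 440, 1500 and 1775, 583 and 350, 65 and 101, 272 and 127). The gate per cell kept 49, 42, 67 and 28 cells, in the order wild-type untreated, wild-type with anti-PD-L1, knockout untreated and knockout with anti-PD-L1, so counting noise enters (853 and 1129, 1210 and 834, 970 higher in wild-type treatment, 968 and 798, 250 and 247, 274 and 281). It also selects among CD8 T cells, as those with a UMI of Ly6c2, Ccr2 or Ighm are left out. All kept cells add melanoma-like and macrophage-like cells in unequal shares. They gave 776 and 949 untreated, 100 higher with anti-PD-L1, 815 and 1422 in wild-type treatment, 137 lower in knockout treatment, 74 higher in both genotype and 115 lower in both treatment comparisons. For the next counts the cause was not tested. The stricter filter gave 573 lower in untreated knockout. It also placed outside the CD8 T cells a cluster of 504 cells, 354 of them knockout untreated, whose CD8 level (1156 CPM) passed and whose CD3 level (2306, against 4662 in the highest cluster) fell just short, so its values mix both changes. Leaving out cycling-like clusters gave 693 there, 112 lower in knockout treatment and 69 lower in both treatment comparisons. The gate without Ly6c2 and Ccr2 gave 535 lower untreated, 174 and 111 with anti-PD-L1, 92 lower in knockout treatment and 18 higher in both genotype comparisons. TMM factors gave 27 higher in knockout with anti-PD-L1. The additive edgeR quasi-likelihood fit, with 1 residual degree of freedom and any interaction taken as error, gave 22 and 12 by genotype. By treatment it gave 137 and 24, within 1.5 times the counts for both treatment comparisons. These are different quantities, as the fit can call genes that are apart in only 1 comparison. Fosl2 and Cnih2, for example, were called higher by genotype but were not higher with anti-PD-L1. At an unadjusted threshold the fit gave 113 and 55 by genotype and 350 and 317 by treatment. Equal weights, no doublet removal, the first listing, another kernel and leaving out each gene's highest cell moved no count past 1.5 times. The kernel gave 364 and 317, 50 and 71, 523 and 951, 134 and 52, 9 and 21, and 94 and 26.

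Of 683 alternative list medians, 548 lay within their counting bounds, 126 outside and 9 had the opposite sign. All kept cells moved 34, leaving out cycling-like clusters 25, the gate per cell 21, the gate without Ly6c2 and Ccr2 16, the stricter filter 12, TMM factors 11, equal weights 6 and the first listing 1. Opposite in sign were, with the gate per cell, memory genes in untreated knockout (−0.033), cytokines in knockout treatment (−0.077), MHC class I in wild-type treatment (−0.20) and homing in untreated knockout (−0.13). All kept cells turned MHC class I in knockout over wild-type with anti-PD-L1 (0.056). Without cycling-like clusters the G2/M median there was −0.28, in a setting that removes the cells named by such genes, and receptor signalling 0.090. The gate without Ly6c2 and Ccr2 turned G2/M in knockout treatment (0.23) and ribosomal proteins in knockout over wild-type with anti-PD-L1 (0.022).

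Of 5294 alternative folds of named genes, 3678 lay within their counting bounds, 1577 outside and 39 were opposite, a label given only where the main fold was over 1.5. Smaller folds that turned, such as Ifng with anti-PD-L1 (−1.90 and −0.27 with the 2 gates), count as outside. With all kept cells, in wild-type treatment these included Gzmf (0.31), Mt2 (−1.23), Id3 (0.26), Slamf6 (0.14), Slc36a3os (0.29), Tcf7 (0.32), Hspa1a (0.52), Serpinb9b (0.42), Lef1 (0.57), Isg15 (−0.062), Hmgb2 (0.088) and Bcl2l1 (−0.61). In untreated knockout over wild-type they were Cd83 (1.24), Capg (0.32), AA467197 (1.16), Id3 (0.34), Slamf6 (0.30) and Hspa1a (0.75), with anti-PD-L1 Cd81 (0.10), and in knockout treatment Mt1 (−0.0097) and Ccl9 (−0.034). The gate per cell turned Gm156 (−1.22), Hspa1a (0.92) and Ifi27l2a (−0.36) in untreated knockout and Ifi27l2a (−0.32) in wild-type treatment. In knockout treatment it turned Mt2 (−0.023), Ifitm1 (−1.24), Gzmb (−0.53), Rgs16 (−0.36), Gzma (−2.49), Ccl9 (−0.37), Ccl5 (−0.077) and Pim1 (−0.19). The gate without Ly6c2 and Ccr2 turned Klri2 in wild-type treatment (−0.39), BC035044 in untreated knockout (−0.14) and Cd83 with anti-PD-L1 (0.21). The first listing turned Gzmd in wild-type treatment (0.50). Without its highest cell per library, Gzmg in wild-type treatment was 4.40, as 394 of its 395 untreated UMIs sat in 1 cell, so that value rests on the 1 UMI left. For the others the cause was not tested, beyond the added cells, the low numbers and the selection by the gates named above.

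Class shares depend on the clustering, and 54 of 96 alternatives moved past the counting interval. They follow in percent of CD8 T cells in the order of libraries above, or for the named libraries. Progenitor-like shares were 27.2, 37.0 and 13.7 in the last 3 libraries with the stricter filter, 62.2, 25.7, 48.4 and 19.6 at resolution 0.5, and 37.8 and 16.6 in wild-type at resolution 1.5. Without cell cycle genes they were 6.07, 17.1 and 16.1 in the first 3 libraries, and 31.1, 17.0 and 18.7 on thinned cells. Wild-type untreated had 20.2 with the first listing and 11.5 without doublet removal, and knockout untreated 19.5 with the other kernel. Cycling-like shares were 0.802, 14.6, 19.1 and 24.0 with the stricter filter, 1.04, 13.7, 13.8 and 23 with the first listing, 1.16, 12.4, 13.1 and 21.1 without doublet removal, and 1.25, 12.3, 13.3 and 19.7 at resolution 0.5. At resolution 1.5 they were 6.32 in wild-type and 39.1 in knockout untreated. Without cell cycle genes they were 0.535, 9.42, 11.6 and 18.3, and on thinned cells 8.90, 15.3, 16.5 and 20.5. Recently stimulated-like shares were 20.5 in knockout untreated and 30.4 with anti-PD-L1 under the stricter filter, 11.8 and 24.6 with the first listing, 33.0 in wild-type with anti-PD-L1 without doublet removal, and 26.9 there and 24.6 in knockout with anti-PD-L1 at resolution 0.5. At resolution 1.5 they were 5.42, 8.87 and 7.62 in the last 3 libraries. For the same reason clusters of 378 cells at resolution 1.5 and of 404 on thinned cells, mostly wild-type untreated (361 and 339), fell outside the CD8 T cells. Why clusters regroup was not tested.

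Of 240 alternative shares of cells with a UMI, 157 moved past the counting interval. No thinning moved 56 of 60, the gate per cell 52, the gate without Ly6c2 and Ccr2 42 and the stricter filter 7. At equal depth and number of cells 3 of the 6 counts between libraries moved past 1.5 times, with 1698, 889 and 1322 genes in pairs with wild-type untreated and 643, 235 and 362 in the others. Depth limits genes under about 20 CPM, such as Prf1, Tet1, Tigit and Tnf.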

Other observations

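No test in this part was run on the patterns after they were seen. Cells other than CD8 T cells are described by their values only, from 920, 69, 190 and 50 melanoma-like and 204, 173, 404 and 181 macrophage-like cells in wild-type untreated, wild-type with anti-PD-L1, knockout untreated and knockout with anti-PD-L1.

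Melanoma-like cells held more of many interferon response and antigen presentation transcripts with knockout T cells in untreated tumours, and of fewer with anti-PD-L1. Untreated, 15 of 23 interferon genes were 1.5-fold higher than with wild-type T cells, with a median log2 fold of 0.73, and 10 of 15 MHC class I genes, with a median of 0.70. With anti-PD-L1 the numbers were 5 of 23 (0.44) and 4 of 15 (0.40). Treatment gave 0.43 over interferon genes with wild-type and 0.10 with knockout T cells. Cd274, the gene of PD-L1 and itself induced by interferon, was at 12.1, 25.0, 25.4 and 52.5 CPM, the invariant chain gene Cd74 at 671, 1635, 2172 and 3005, and B2m, the shared chain of MHC class I, at 4381, 5961, 7191 and 7896. H2-K1 was at 490, 808, 899 and 957. The interferon-induced chemokines Cxcl9 (24.0, 97.0, 154 and 63.9) and Cxcl10 (523, 595, 741 and 452) were lower with knockout than with wild-type T cells under anti-PD-L1. Transcripts of host cells in these clusters moved as well, Lyz2 of macrophages with log2 folds of 1.58 and 0.99 for knockout over wild-type, and untreated Ccl5 with 1.78 and Xist with 1.58, whereas the macrophage gene C1qa had −0.89 untreated, so the values do not show that melanoma cells alone changed. Cell cycle genes ran the other way, most clearly with anti-PD-L1, where 19 of 24 G2/M genes (median −1.05) and 17 of 21 S phase genes (−0.96) were lower with knockout T cells. Untreated, only 8 of 24 (−0.46) and 2 of 21 (−0.29) were lower. Some of these libraries hold few melanoma-like cells, and the values have no replicates.

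Macrophage-like cells also held more of some interferon-induced transcripts in tumours with knockout T cells. Cd274 was at 65.3, 108, 108 and 185 CPM and the chemokine Cxcl9, which draws T cells, at 511, 650, 967 and 1073, but Cxcl10 at 212, 409, 215 and 505. Interferon genes had a median of 0.50 for knockout over wild-type untreated, with 11 of 29 higher, and 0.46 with anti-PD-L1, with 8 of 29 higher. Apoe, a lipid carrier, was at 11448, 7359, 5866 and 5954, and Mrc1, the mannose receptor of alternatively activated macrophages, at 238, 133, 113 and 106. Nos2, which makes nitric oxide, was at 23.8, 106, 72.6 and 83.0. G2/M genes were lower outside wild-type untreated, with 14 of 16 lower in knockout untreated (−1.17) and 16 of 16 lower in wild-type with anti-PD-L1 (−1.53). Melanoma transcripts in these cells fell alongside, Dct at 108, 10.9, 13.7 and 8.07 and Pmel at 86.1, 10.0, 10.4 and 2.31, so the change is not shown to be one of macrophages. Immediate early and heat shock genes, which respond to tissue handling, had a median of 0.62 in knockout over wild-type untreated, −0.00 with anti-PD-L1, 1.15 in wild-type treatment (13 of 20 higher) and 0.34 in knockout treatment. In melanoma-like cells the comparisons with wild-type untreated gave 0.02 and 0.04.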
